A study of Mus musculus with 2 samples.

How the data were processed

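The deposited files hold raw UMI counts per gene and cell for 2 wild-type samples, as the authors filtered the cells. They hold 32183 gene symbols, 2561 cells of WT sample 1 and 1392 cells of WT sample 2. The filters the authors put on the cells were not given in the sources used here. Per the submitters' processing notes, reads were aligned to mm10 with Cell Ranger 7 and analysed under R 4.2.0 with DESeq2 1.34.0. Those notes leave out the Seurat version. The deposited cell tables, per the file headers, hold a score per cell on 14 principal components and 2 UMAP axes. They carry no cell names, and their rows were taken to follow the order of the barcodes. Ranges were written per sample and per cluster, but only those per sample, which need no such order, are reported. No antibody-tag name was found among the 32183 symbols (0 tags), and protein tags were not analysed here. Positions came from GENCODE M21 on mm10 by gene symbol, which placed 31390 symbols (97.5%).

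The 2 samples were treated as different libraries, as named. They shared 0 barcodes, which does not by itself show separate libraries. Their summed profiles differed by more than counting error (chi-square over degrees of freedom 4.30, 12702 genes), which a different mix of cells alone can give. The prefix of each barcode was read as the capture lane, which gave 1320 and 1241 cells of WT sample 1 and 673 and 719 of WT sample 2 in lanes 1 and 2.

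Counts were log-normalized to 10000 UMIs per cell in scanpy 1.11.5 (Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3). The 2500 most variable genes were chosen. All genes of the fixed lists, mitochondrial, ribosomal protein and immunoglobulin genes, unnamed Gm genes, Xist and Tsix were left out, which left 2079. These were scaled with a maximum of 10 and reduced to 25 principal components. A graph of 15 neighbours was then split by Leiden (leidenalg 0.10.2) at resolution 1.0, with seed 0. This gave 17 clusters, and resolution 2.0 gave 24. Clusters were named by the level of fixed marker genes for ILC2, ILC3, ILC1 or NK, T, B or plasma, myeloid, mast cell or basophil, epithelial, and stromal or endothelial cells. The ILC3-like clusters were then named by NCR+ and LTi-like (CCR6+) subset markers. Clusters that met no rule stayed unnamed.

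The main test was edgeR 4.0.16 (R 4.3.3, limma 3.58.1) on UMI sums per sample and cell group, with at least 20 cells per sum. It used TMM scaling, the edgeR expression filter, a quasi-likelihood fit with the sample as a block, and Benjamini-Hochberg adjustment over all genes kept. The threshold was an adjusted p of 0.05. Each cell group came from both samples, so the sample block pairs the groups by construction. Comparison A (ILC3-like against ILC2-like) was fitted on 12 sums with 5 residual degrees of freedom. Comparison B (each ILC3-like cluster against the average of the other 2) had 6 sums and 2 degrees of freedom. Comparisons C (Il22 status) and D (Pdcd1 status) had 4 sums and 1 degree of freedom each. The prior degrees of freedom, borrowed across genes, had medians of 12.6, 24.1, 12.4 and 20.6, so p-values rest mostly on a spread shared by all genes. The biological coefficients of variation were 11.0, 8.53, 5.73 and 7.63%. A cell was called positive for a gene at 1 or more UMIs. These choices were written before the data were examined.

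Levels are edgeR CPM, counts scaled to TMM library sizes, as mean ± SD of n = 2 samples. Log2 fold changes are from the fit with the standard error (SE), and the value in each sample is the log2 ratio with 1 CPM added. Pooled CPM were taken from the summed UMIs of a cluster, with no TMM scaling. In comparison B the log2 fold change is taken against the average of the log2 levels of the other 2 clusters, and the CPM of the others is their arithmetic mean. Shares of cells carry exact Clopper-Pearson 95% intervals, which hold counting error alone. For shares at equal depth each cell was thinned to 3000 UMIs, and 616 shallower cells were left out. Where a group had 0 UMIs, a fold was given as a lower limit from a floor of 3 UMIs over the group. Where it had 1 to 3 UMIs, levels were given and no fold.

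Named genes followed one rule. Pdcd1 and Il22 were always named. Genes past the threshold, with the same direction in both samples and at least 50 CPM in the higher group, gave the 12 largest rises and the 12 largest falls in log2 fold change. Left out were the gene that defined the groups, mitochondrial and ribosomal protein genes, unnamed genes and, between classes or clusters, genes used for clustering or naming. In comparisons C and D genes used for clustering or naming were not left out. Up to 4 examples per list were then taken by the smallest p.

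The 15 fixed gene lists were checkpoint and costimulatory receptors, effector cytokines, the IL-23, IL-1 and STAT3 axis, aryl hydrocarbon receptor targets, the Notch pathway, glycolysis, lipid and sterol synthesis, polyamine synthesis, antioxidant enzymes, oxidative phosphorylation, cell cycle, immediate early and dissociation response, NF-kB targets, tissue residency and migration, and MHC class II presentation. Each was counted gene by gene and tested with camera (limma) at a preset correlation of 0.01, again with an estimated correlation, and with fry, which asks whether the genes move on balance one way or in either direction. The list tests were adjusted over the 15 lists. With an estimated correlation camera rests on the few residual degrees of freedom of the fit. A list can therefore hardly pass that version in comparisons B, C and D.

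The fits were tested on simulated data, drawn from the means, library sizes and dispersions of the real sums, with changes put into a known set of genes. They recovered 97, 84, 75 and 64% of 2-fold changes and 100, 100, 97 and 96% of 4-fold changes in comparisons A, B, C and D. False calls were 21, 15, 8 and 10 among 9295, 8533, 9684 and 9336 unchanged genes. Changes went only into genes with an expected count of at least 10 in the smallest sum, so recovery at lower counts was not tested. Genes were drawn independently, with no sample effect and no choice of cells by a UMI. The false calls therefore do not test the status comparisons C and D for errors of that kind.

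Alternatives tried were no sample block, DESeq2 1.42.0 as the test, DESeq2 size factors, no expression filter, each lane alone, finer clusters, cells with under 500 genes or over 10% mitochondrial UMIs left out (63 cells), high Scrublet scores left out, cycling cells left out, 2 or more UMIs to call a cell positive, the largest cluster alone, and cells paired within sample and cluster by nearest depth. Figures were drawn with matplotlib 3.10.9.

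Some choices were made after values had been seen. The automatic Scrublet threshold called 0.273 and 0.216% of the cells, so a cut at the top 8% of scores was used in its place. All cells tied at the cut were called as well (205 and 126 cells, 8.00 and 9.05%). The naming thresholds were set after the marker levels were seen. The level of a class was the mean over its markers of CPM divided by that of the highest cluster. A class name needed a level of 0.35, at least 3 markers at 20 CPM and, among the 10 leading genes, no more markers of another class. For ILC and T cell names the median UMIs had to be at most 1.5 times the sample median. A subset name needed a level of 0.6 with the other subset at most 0.4. A rule that leading T cell receptor genes bar an ILC name was added as well, and it left a cluster with high Trdc without a name. The alternatives of single lanes, of adding the Trdc cluster to the ILC3-like cells, of matching for depth alone, of pairs in the same cluster within 10% in depth and of lists without naming markers were also chosen after the data were seen. The ratios per sample in comparison B were first taken against the arithmetic mean of the other clusters and then changed to match the contrast.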

Results

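Innate lymphoid cells (ILCs) of the small intestine were profiled by single-cell RNA sequencing in female C57BL/6 wild-type mice aged 6 to 8 weeks. Live CD45+ CD127+ cells were sorted after exclusion of cells bearing B220, CD11b, CD19, CD3, F4/80, NK1.1, TCRb or TER119. The data set held 3953 cells in 2 samples, with no treated or mutant group. WT sample 1 had 2561 cells and 16663917 UMIs, with a median of 5223 UMIs and 2122 genes per cell. WT sample 2 had 1392 cells and 8540478 UMIs, with a median of 5057 UMIs and 2036.5 genes. Mitochondrial UMIs made up a median of 1.62 and 1.67%. The labels name 3 mice and 2 samples without saying how they map. With the sample as a block, p-values measure only how far differences between cell groups varied between these 2 samples, which may be technical. That spread was estimated mostly from all genes together.

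The work asked where Pdcd1, which encodes the inhibitory receptor PD-1, is transcribed among gut ILCs and how it relates to Il22, which encodes the cytokine IL-22. Genes were known by symbol alone. Pdcd1 lies on chromosome 1 at 94038305 to 94052553 on the minus strand of mm10, and Il22 on chromosome 10 at 118204942 to 118210047 on the plus strand. Il22 has a near-identical neighbour, Iltifb, on the minus strand at 118289629 to 118295038, and reads shared by both genes may have been lost from either.

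To see which cells the sort held, clusters were named by marker genes. ILC3-like cells, with Rorc, Il23r and Il22, were the largest class, at 35.7% of cells in WT sample 1 (95% interval 33.9 to 37.6, 915 cells) and 50.4% in WT sample 2 (47.8 to 53.1, 702 cells). ILC2-like cells, with Gata3, Il1rl1 and Il5, made up 20.1% (18.5 to 21.7, 514 cells) and 18.0% (16.05 to 20.2, 251 cells). ILC1 or NK-like cells (Xcl1, Gzma) made up 5.66% (4.80 to 6.63) and 3.52% (2.62 to 4.63), and T cell-like cells 9.68% (8.57 to 10.9) and 5.96% (4.78 to 7.34). B or plasma cell-like cells (Ebf1, Cd79a, Jchain) reached 6.68% (5.74 to 7.71) and 6.25% (5.04 to 7.65). Myeloid-like cells made up 2.66% (2.07 to 3.35) and 2.16% (1.46 to 3.06), and epithelial-like cells (Tff2, Muc6, Krt8) 0.742% (0.447 to 1.16) and 0.216% (0.0445 to 0.629). Clusters with no name held 18.8% (17.3 to 20.3) and 13.4% (11.7 to 15.3). The largest of these carried Trdc, Cd163l1, Blk and Il17a. With finer clusters the ILC3-like share was 27.4 and 41.7% and the T cell-like share 12.3 and 8.98%. Finer clusters 6 and 10 (239 and 188 cells) had ILC3 as best class but were left unnamed by the rule on leading genes. A finer cluster with Lef1 (111 cells) was named T cell-like. The sort and the 2 samples alone set these shares, and the intervals hold counting error only.

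Within the ILC3-like cells, cluster 0 carried the natural cytotoxicity receptor gene Ncr1 and was named NCR+. Cluster 8 carried Nrp1 and Ccr6, as lymphoid tissue inducer (LTi) cells do, and was named LTi-like. Cluster 1 had high Il22, Ptprm and Myof and met neither name. Cluster 0 held 70.4 and 54.4% of the ILC3-like cells in WT samples 1 and 2, cluster 1 held 17.9 and 34.2%, and cluster 8 held 11.7 and 11.4%. Haemoglobin genes led the list of genes for cluster 0, but Hbb-bs came from 6 of its 1026 cells (0.585%), and a single cell held 890 of the 1757 UMIs.

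The first comparison asked whether Pdcd1 differed between ILC3-like and ILC2-like cells. Pdcd1 was lower in ILC3-like cells, at 134 ± 66.2 CPM against 225 ± 10.7 CPM in ILC2-like cells (mean ± SD, n = 2). The log2 fold change was −0.80 (SE 0.27, edgeR adjusted p = 0.0316), with −1.30 in WT sample 1 and −0.36 in WT sample 2. This class value rests on the mix of ILC3-like clusters, which differed between the samples. In pooled CPM Pdcd1 was at 18.4 and 5.83 in cluster 0, 137 and 234 in cluster 1 and 302 and 573 in cluster 8, against 203 and 216 in ILC2-like cells. A Pdcd1 UMI was seen in 14.9% of ILC3-like cells of WT sample 1 (12.6 to 17.3) and 20.1% of WT sample 2 (17.2 to 23.2). In ILC2-like cells the shares were 34.8% (30.7 to 39.1) and 33.1% (27.3 to 39.3). At 3000 UMIs per cell they were 11.8 and 16.3% (119 and 102 shallow cells left out) against 31.1 and 27.2% (103 and 60 left out). The lower Pdcd1 of ILC3-like cells no longer passed without the sample block (−0.75, adjusted p 0.0773), under DESeq2 (−0.79, 0.182), in lane 1 (−0.89, 0.0692) or lane 2 alone (−0.61, 0.0693), or with finer clusters (−0.46, 0.187). Adjusted p over all alternatives ran from 7.99e-05 to 0.187.

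Beyond Pdcd1, 1535 of 10075 genes were higher in ILC3-like than in ILC2-like cells and 1454 were lower, 2989 in all. The classes were made from the expression of these same cells, and genes used for clustering were counted too. Such genes differ in part by construction. Il22 was at 992 ± 155 CPM against 9.77 ± 3.66 CPM (log2 6.72, SE 0.46), but it served to name the class. Among genes used neither for clustering nor for naming, the carbonic anhydrase gene Car2 was at 593 ± 15.1 CPM against 6.03 ± 1.03 CPM (log2 6.53, SE 0.27, adjusted p 5.75e-12). The Fc receptor signalling chain Fcer1g was at 353 ± 12.7 CPM against 6.28 ± 1.11 CPM (5.85, SE 0.25). Further rises were the olfactory receptor gene Olfr60 (7.09), Rbpms2 (5.58), Psd2 (5.38), Itih5 (5.33), the adhesion gene Jaml (5.32), Ppp1r3b (4.93) and Pram1 (4.70). Klrb1f (73.3 CPM, 693 UMIs against 2), Upp1 (65.6 CPM, 609 against 2) and Lingo4 (53.1 CPM, 481 against 3) were close to absent from ILC2-like cells. The retinoid X receptor gene Rxrg had 0 UMIs in ILC3-like cells and 174 in ILC2-like cells (51.7 CPM), at least 142-fold lower. The sterol synthesis gene Cyp51 was lower at 62.9 ± 4.68 CPM against 375 ± 15.3 CPM (−2.58, SE 0.17, adjusted p 1.70e-09). Other falls were the costimulatory receptor Cd27 (−4.10), the adenosine receptor Adora2a (−3.75), Pou2f2 (−3.43), the flagellin sensor Naip5 (−3.18), Rasgrp4 (−3.11), the delta chain segment Trdv4 (−3.05), Zfp704 (−2.72), Klk8 (−2.67), Ets2 (−2.61) and Spcs3 (−2.51).

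Called NF-kB targets and immediate early genes were mostly higher in ILC3-like than in ILC2-like cells, while checkpoint receptors went both ways. Of 19 checkpoint and costimulatory receptors, 6 were higher in ILC3-like cells, 7 lower and 6 not past the threshold (7 higher and 8 lower adjusted over the list alone). Ctla4 was at 122 ± 28.7 CPM against 34.8 ± 2.00 CPM (log2 1.83), while the PD-1 ligand gene Pdcd1lg2 was at 19.9 ± 2.20 against 79.9 ± 0.566 (−1.99) and Cd200r1 at 91.3 ± 33.6 against 349 ± 18.8 (−1.98). Among 20 effector cytokines, 11 were higher and 6 lower (11 and 6 adjusted over the list alone), and 12 of the 20 were naming markers, such as Il4 (−4.94) and Il5 (−7.37). The growth factor gene Hbegf, no marker, was at 215 ± 16.2 against 12.5 ± 3.89 CPM (3.99). The IL-23, IL-1 and STAT3 axis had 10 of 21 genes higher and 4 lower (10 and 5 adjusted over the list alone), with Il18r1 at 878 ± 52.7 against 102 ± 10.8 CPM (3.12). Il23r (6.81), Il1r1 (5.78) and Il2rb (1.88) of this list were naming markers. Of 15 NF-kB targets, 10 were higher and 1 lower (10 and 1 adjusted over the list alone), among them the activation marker Cd83 (2.66), Icam1 (2.38) and Bcl2a1d (2.21), with Nfkb1 lower (−0.97). Immediate early and dissociation genes were higher in 14 of 25 and lower in 1 (16 and 1 adjusted over the list alone), as in Atf3 (1.87), Egr1 (1.73), Btg2 (1.41) and Nr4a3 (1.15). Tissue residency and migration had 9 of 17 higher and 3 lower (9 and 3 adjusted over the list alone), with the integrin Itga1 (4.35), the naming marker Cxcr3 (3.65), Gpr183 (1.30) and Rgs2 (−1.44). Of 9 MHC class II presentation genes 2 were higher (2 and 0 adjusted over the list alone), the invariant chain Cd74 at 239 ± 38.5 against 167 ± 11.3 CPM (0.52) and the naming marker H2-Aa (0.57).

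Called genes of the polyamine list were all higher in ILC3-like than in ILC2-like cells, and those of lipid and sterol synthesis mostly lower. Glycolysis had 9 of 20 genes higher and 5 lower (9 and 5 adjusted over the list alone). The hexokinase gene Hk2 was at 847 ± 14.3 against 80.7 ± 7.09 CPM (log2 3.40, adjusted p 4.24e-10) and Pfkfb3 at 550 ± 63.2 against 65.2 ± 13.5 (3.02), while Ldha (−1.09) and the lactate carrier Slc16a1 (−2.87) were lower. Lipid and sterol synthesis had 1 of 24 higher and 9 lower (1 and 9 adjusted over the list alone), with Scd2 (−2.02), Elovl5 (−1.56) and Acsl4 (−1.48) beside Cyp51. All 5 genes of the polyamine list past the threshold, of 13, were higher (5 and 0 adjusted over the list alone). The rate-limiting Odc1 was at 2257 ± 411 against 584 ± 71.0 CPM (1.94), with Smox (3.01), Azin1 (2.10) and Sat1 (1.37). Smox, Sat1 and the also called Oaz1 act in polyamine breakdown or against Odc1, so the list does not track synthesis alone. Antioxidant enzymes had 3 of 23 higher and 5 lower (3 and 6 adjusted over the list alone), as in Srxn1 (2.43), Gpx1 (2.03), Glrx (−2.18) and Gpx4 (−0.73). Of 35 oxidative phosphorylation genes 1 was higher and 3 lower (1 and 0 adjusted over the list alone), with Cox6c at 0.60 and Cox7a2 at −0.46. In the cell cycle list 0 of 13 were higher and 2 lower (0 and 2 adjusted over the list alone), Mcm6 (18.0 against 35.1 CPM) and Mcm3 (15.3 against 26.1 CPM). Of 6 aryl hydrocarbon receptor targets 0 were higher and 3 lower (2 and 3 adjusted over the list alone). The receptor gene Ahr itself was at 130 ± 6.64 against 313 ± 50.7 CPM (−1.27, adjusted p 2.80e-06), with Ahrr (−0.92) and Tiparp (−0.36). The Notch pathway had 2 of 10 higher and 3 lower (3 and 3 adjusted over the list alone), with Adam17 (0.54), Adam10 (−0.67), Maml2 (−0.40) and the naming marker Hes1 (−2.97).

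As lists, 5 of 15 passed camera between ILC3-like and ILC2-like cells. NF-kB targets (adjusted p = 0.000439, or 0.152 with an estimated correlation), immediate early genes (0.000439, or 0.362), the IL-23, IL-1 and STAT3 axis (0.0398, or 0.287) and polyamine synthesis (0.0406, or 0.315) were higher. Lipid and sterol synthesis was lower (adjusted p = 0.0109, or 0.315 with an estimated correlation), so 0 lists passed with an estimated correlation, and 2 had an unadjusted p under 0.05. With the naming markers left out of the lists, an alternative chosen after seeing the data, the IL-23, IL-1 and STAT3 axis no longer passed (18 genes, adjusted p 0.5102). Effector cytokines then passed (8 genes, 0.0213, or 0.265 with an estimated correlation), and the other 4 lists still did. The other lists had adjusted p of 0.129 (effector cytokines, up), 0.142 (tissue residency and migration, up), 0.271 (glycolysis up, MHC class II up, cell cycle down), 0.516 (aryl hydrocarbon receptor targets and antioxidant enzymes, down), 0.561 (checkpoint receptors, down) and 0.625 (Notch and oxidative phosphorylation, down). Oxidative phosphorylation had a median log2 fold change of 0.02 and a mean of −0.01. In fry, 8 lists passed on balance in one direction and 12 with genes in either direction.

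To place Pdcd1 among the ILC3-like subsets, each cluster was set against the average of the other 2. Pdcd1 rose from the NCR+ cluster 0 (12.2 ± 8.72 CPM) through cluster 1 (191 ± 75.5 CPM) to the LTi-like cluster 8 (441 ± 201 CPM, mean ± SD, n = 2). Its log2 fold change was −4.27 in cluster 0 (SE 0.25, adjusted p 5.64e-13, samples −3.40 and −5.76), 1.25 in cluster 1 (SE 0.21, 2.72e-04, samples 0.87 and 1.94) and 3.02 in cluster 8 (SE 0.19, 2.43e-12, samples 2.53 and 3.81). Cluster 1 lay below cluster 8, so its value above 0 comes from the low level of cluster 0. Mean Il22 had the same order at 558 ± 56.0, 1519 ± 19.3 and 1665 ± 170 CPM, with log2 fold changes of −1.51 (SE 0.08), 0.66 (SE 0.07) and 0.85 (SE 0.07). Its step from cluster 1 to cluster 8 was not tested. The Il22-positive share in these 2 clusters was 66.5 and 76.6% in WT sample 1 but 69.2 and 67.5% in WT sample 2. Pdcd1 in cluster 1 no longer passed without the sample block (1.33, adjusted p 0.0522), under DESeq2 (1.35, 0.9996) or in lane 2 alone (1.06, 0.158). Its value stayed above 0, and adjusted p over all alternatives ran from 5.49e-15 to 0.9996.

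A Pdcd1 UMI was found in 4.04% of cluster 0 cells of WT sample 1 (2.65 to 5.86) and 2.09% of WT sample 2 (0.908 to 4.08), at median depths of 4954 and 4640 UMIs. In cluster 1 the shares were 26.8% (20.2 to 34.3) and 34.6% (28.6 to 41.0) at 5881 and 5156.5 UMIs. The LTi-like cluster 8 reached 61.7% (51.8 to 70.9) and 62.5% (51.0 to 73.1) at 6546 and 6072.5 UMIs. With every cell thinned to 3000 UMIs the Pdcd1 shares were 3.19 and 1.86% (79 and 59 cells left out), 19.3 and 27.1% (29 and 37) and 52.1% and 37 of 74 cells (11 and 6). Epithelial-like cells, which should lack Pdcd1, had it in 0 of 22 cells, which allows up to 15.4%, at a median of 25970 UMIs against 5092 in ILC3-like cells. Whether the few Pdcd1 UMIs of cluster 0 came from free RNA was not tested. Il22 was seen in 52.6% of ILC3-like cells, in 13 of 765 ILC2-like cells (1.70%, median 4565 UMIs) and in 2 of 22 epithelial-like cells (9.09%).

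**Figure D1:**
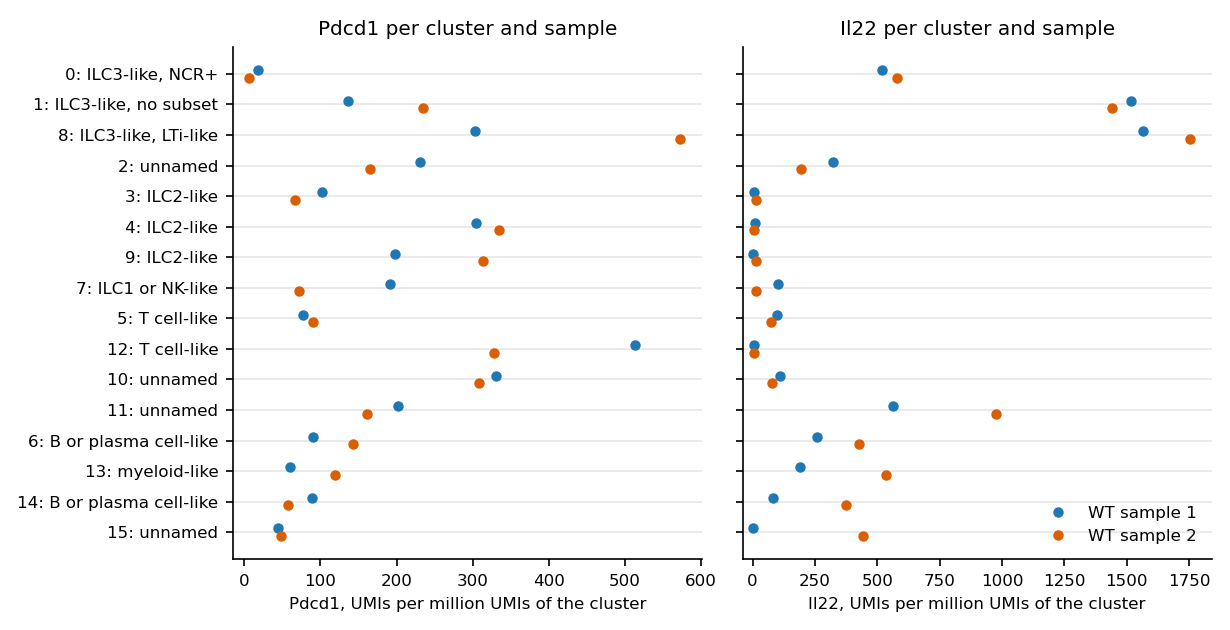
Pdcd1 (left) and Il22 (right) in CPM of each cluster, pooled, (x axis) for 16 clusters (y axis); each point is one sample (blue WT sample 1, orange WT sample 2), and the epithelial-like cluster 16 is left out. In WT samples 1 and 2 Pdcd1 was at 18.4 and 5.83 in cluster 0, 302 and 573 in cluster 8 and 514 and 328 in cluster 12.

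In the NCR+ cluster 0, 693 of 9023 genes were higher and 851 lower than in the other ILC3-like clusters. These counts, like those of the other ILC3-like clusters below, include genes used for clustering, which differ in part by construction. Among the named rises were Slamf7 (61.1 against 10.6 CPM, log2 2.47), the gut-homing receptor Ccr9 (259 against 63.0, 2.08), the chemokine Ccl4 (164 against 46.4, 1.87), the kinase Lck (142 against 40.6, 1.84), Ctsw (1.75) and Itga1 (1.71). Irf7 (1.94), Irak3 (1.68), Gimap4 (1.67), Lgals1 (1.63), Pik3r5 (1.48) and Ltb4r1 (1.41) were higher as well, with adjusted p for these rises from 3.36e-12 (Gimap4) to 3.62e-06 (Ltb4r1). Besides Pdcd1, the largest falls were the nucleosome-binding gene Hmgn3 (6.21 against 118 CPM, −3.88), the tetraspanin Cd81 (5.27 against 85.6, −3.75) and the neuropeptide receptor subunit Ramp1 (4.85 against 72.8, −3.53). Cryaa (−2.56), Slc6a13 (−2.28), Apobec1 (−2.14), Cd83 (−2.05), Bst2 (−1.82), Cxcr4 (−1.76), Gramd4 (−1.68) and Slc15a3 (−1.67) were also lower.

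In cluster 1, which had no subset name, 264 genes were higher and 96 lower. Pdcd1, higher by this contrast, lay between its levels in clusters 0 and 8. Beside Pdcd1, the arginase gene Arg1 (295 against 169 CPM, log2 0.85), the cytokine Csf2 (152 against 96.2, 0.80), Rell1 (1.02), Frmd4b (0.96), Cd200r4 (0.95), Adgrg3 (0.94), Asphd2 (0.89), Gpr34 (0.82), Ltb4r1 (0.79), Azin1 (0.78) and Mpzl3 (0.78) were higher. Cd200r4, Gpr34 and Ltb4r1 were among the largest falls of cluster 8. The contrasts of the clusters sum to 0, so for these genes cluster 0 lay above cluster 1. Their rises here are the fall of cluster 8 seen from the other side. Csf2 was also called higher in cluster 0 and lower in cluster 8, so its rise here is at least in part that fall. The falls included the antigen presentation genes H2-Eb1 (43.2 against 148 CPM, −1.27), Cd74 (141 against 451, −1.18) and H2-Ab1 (58.8 against 127, −0.88). Cluster 1 was here at the level of cluster 0 (H2-Eb1 46.3, Cd74 137 and H2-Ab1 61.7 CPM), so these falls are the rise of cluster 8 seen from the other side. The inhibitory receptor Ctla4 was at 57.2 against 123 CPM. Bcl2a1b (−1.07), Serpina3g (−0.93), Klrb1f (−0.88), Uck2 (−0.87), Rab27a (−0.77), Amfr (−0.74), Bcl10 (−0.69) and Sppl2a (−0.67) were lower too, with adjusted p for these genes from 1.28e-06 (Azin1) to 0.0489 (Mpzl3). Of 25 named genes of cluster 1 other than Pdcd1, 14 no longer passed under DESeq2, 14 without the sample block, 18 in lane 1 alone and 12 in lane 2 alone.

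The LTi-like cluster 8 had 820 genes higher and 643 lower. The MHC class II invariant chain Cd74 was at 765 ± 237 CPM against 139 ± 3.77 (log2 2.45, SE 0.12, adjusted p 1.22e-14), with H2-Eb1 at 250 against 44.7 CPM (2.46). The Notch ligand Dll1 (59.9 against 8.95 CPM, 4.17), Piwil4 (58.7 against 1.75, 5.61), Parvb (60.3 against 3.12, 4.74), Hmgn3 (196 against 23.0, 3.66), Cd81 (131 against 22.7, 3.15), Ramp1 (112 against 19.0, 3.08), Impa2 (2.64) and Ecm1 (2.54) were higher. Plb1 had 76 UMIs in cluster 8 (51.1 CPM) and 1 in the other clusters. The largest falls were Cd200r4 (18.9 against 99.5 CPM, −2.30), Ltb4r1 (−2.20), Irak3 (−2.01), Itga1 (27.3 against 108, −1.91), Gimap4 (−1.86), Cd244a (−1.86) and the ectonucleotidase Nt5e (65.1 against 224, −1.80). Gpr34 (−1.73), Slc7a6 (−1.67), Rbpms2 (−1.64), Irf7 (−1.63) and Lck (−1.57) were lower as well.

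The next comparison asked what set Il22-positive apart from Il22-negative ILC3-like cells. Pdcd1 was higher in Il22-positive cells, at 166 ± 77.4 CPM against 86.0 ± 37.2 CPM (mean ± SD, n = 2, log2 0.94, SE 0.11, adjusted p 4.94e-04, samples 0.89 and 0.97). The groups held 445 and 405 positive cells (median 5667 and 5378 UMIs) and 470 and 297 negative cells (4661 and 4504 UMIs) in WT samples 1 and 2. The difference went with the cluster mix. Of the Il22-positive cells 57.1 and 45.7% were in cluster 0, 24.5 and 41.0% in cluster 1 and 18.4 and 13.3% in cluster 8, against 83.0 and 66.3%, 11.7 and 24.9% and 5.32 and 8.75% of the Il22-negative cells. In cells paired within cluster by nearest depth Pdcd1 was at 0.16 (adjusted p 0.844), though positive cells stayed deeper (median 5576.5 and 5186 against 5411.5 and 4564 UMIs). With pairs within 10% in depth, chosen after seeing the data, the medians were 5448 and 4816 against 5473 and 4816 UMIs, and Pdcd1 was at 0.08 (0.909). In the largest cluster alone Pdcd1 turned to −0.28 (0.892). It was smaller but still passed with finer clusters (0.55, 0.0244) and with the Trdc cluster added (0.47, 0.0179). The call also ended without the sample block (0.99, 0.493) and in lane 1 alone (0.80, 0.0981), and adjusted p over all alternatives ran from 8.30e-13 to 0.909.

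By Il22 status 181 of 10118 genes were higher and 94 lower, 275 in all. Among the largest rises were the CD30 ligand Tnfsf8 (95.2 against 32.6 CPM, log2 1.61), Nrp1 (208 against 94.1, 1.18) and Tox2 (67.3 against 31.1, 1.23). The chemokine gene Cx3cl1 was at 66.5 against 20.2 CPM (1.67) and the angiogenic factor Vegfa at 108 ± 8.43 against 46.8 ± 1.07 (1.20). Csmd1 was at 71.2 ± 81.1 against 9.68 ± 8.59 CPM (2.90), with an SD above its mean. Palld (2.05), the kinase Blk (1.55), Igfbp7 (1.40), Fam167a (1.30), Dlc1 (1.21) and Ankrd33b (1.21) completed the rises. The largest named fall was that of the transcription factor Tbx21, at 58.8 ± 11.9 against 133 ± 9.38 CPM (−1.16, adjusted p 2.59e-04), before Nkg7 (45.8 against 95.9, −1.03), Klrb1c (57.0 against 113, −0.98), Klrc1 (−0.92) and the chemokine Xcl1 (−0.88). Irf7 (−0.93), Lin52 (−0.89), Kcnq5 (−0.88), Slc6a20a (−0.86), Lgals1 (−0.78), Sntb1 (−0.76) and St3gal6 (−0.72) were also lower. Nrp1 was a naming marker of the LTi-like subset, and Tbx21 and Xcl1 of the NCR+ subset. Tnfsf8, Nrp1, Cx3cl1 and Csmd1 were among the leading genes of cluster 8, and Slc6a20a of cluster 0. These genes therefore restate the cluster mix in part. Of the 275 genes, 48 stayed among the 54 called in cells paired within cluster by nearest depth, where 32 of 50 named genes no longer passed. Only 13 genes were called with pairs within 10%, and 45 of the 50 no longer passed. Without the sample block 0 genes passed (838 at an unadjusted p under 0.05), and DESeq2 called 35, and the count ran from 0 to 546 over all alternatives. Xcl1 turned with finer clusters (0.0111), Kcnq5 in lane 1 alone (0.0178), and Blk (−0.47) with the Trdc cluster added.

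Of the fixed lists by Il22 status, effector cytokines had the most genes past the threshold, 8 of 16 other than Il22. In Il22-positive cells 5 of them were higher and 3 lower (8 and 4 adjusted over the list alone), with the RANK ligand Tnfsf11 at 1168 ± 116 against 719 ± 55.8 CPM (log2 0.70, adjusted p 4.02e-05), Il17f (1.90) and Il17a (2.55). Il17a turned to −0.0301 with the Trdc cluster added. The IL-23, IL-1 and STAT3 axis had 3 of 21 higher and 1 lower (7 and 1 adjusted over the list alone), with Il1r1 (0.69), Socs3 (0.88), Socs1 (0.68) and Il18r1 (−0.37). Of 17 checkpoint receptors 1 was higher, Pdcd1, and 1 lower, Cd226 (−0.51) (2 and 2 adjusted over the list alone). Among 24 immediate early genes 0 were higher and 4 lower (2 and 7 adjusted over the list alone), with Hspa1b (−0.69), Hsph1 (−0.56), Hspa1a (−0.46) and Dusp1 (−0.33). NF-kB targets had 2 of 15 higher (3 and 0 adjusted over the list alone), Cd83 (0.70) and Nfkbia (0.23). Tissue residency and migration had 3 of 15 higher and 1 lower (3 and 6 adjusted over the list alone), with Cxcr4 (0.62), Itga4 (0.57), Gpr183 (0.27) and Itga1 (−0.55). Glycolysis had 2 of 19 higher (2 and 0 adjusted over the list alone), Pfkfb3 (0.63) and Hk2 (0.41), and polyamine synthesis 2 of 13 (2 and 0), Azin1 (0.45) and Odc1 (0.42). A single gene was higher in the Notch pathway (Notch2, 0.37, of 10), lipid and sterol synthesis (Idi1, 0.73, of 21), antioxidant enzymes (Gpx1, 0.42, of 21) and oxidative phosphorylation (Cox6c, 0.29, of 35), each 1 and 0 adjusted over the list alone. In aryl hydrocarbon receptor targets (6), cell cycle (13) and MHC class II (9) 0 genes passed, with Ahr at −0.14 (adjusted p 0.643), Stmn1 at 16.5 against 8.50 CPM (0.194) and H2-Ab1 at −0.21 (0.512). In camera 0 of 15 lists passed (smallest adjusted p 0.193, 3 at an unadjusted p under 0.05), and 0 with an estimated correlation (0.807). In fry the immediate early list passed (adjusted p 0.0414). Checkpoint receptors tested down with a median log2 of −0.06 and a mean of 0.05, and lipid synthesis tested up with a median of −0.04 and a mean of 0.06.

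The last comparison turned the question round and asked what set Pdcd1-positive ILC3-like cells apart. Il22 was higher in Pdcd1-positive cells, at 1668 ± 250 CPM against 801 ± 98.6 CPM (mean ± SD, n = 2, log2 1.05, SE 0.06, adjusted p 1.05e-10, samples 1.03 and 1.08). The positive group held 136 and 141 cells (median 6789.5 and 5186 UMIs), the negative group 779 and 561 cells (5018 and 4933 UMIs). Of the Pdcd1-positive cells 19.1 and 5.67% were in cluster 0, 32.4 and 58.9% in cluster 1 and 48.5 and 35.5% in cluster 8, against 79.3 and 66.7%, 15.4 and 28.0% and 5.26 and 5.35% of the Pdcd1-negative cells. In cells paired within cluster by nearest depth, Il22 was at 0.32 and no longer passed (adjusted p 0.0825), with medians of 6523 and 5035 against 6027 and 4930 UMIs. With pairs within 10% in depth (6053 and 4933 against 6072 and 5070.5 UMIs) Il22 was at 0.40 and passed (0.00791). Other alternatives gave Il22 from 0.75 to 1.24, and adjusted p over all alternatives ran from 1.62e-52 to 0.0825.

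By Pdcd1 status 617 of 9796 genes were higher and 437 lower, 1054 in all. The largest named rise was Bend4 (3.76), and Cd4 was at 69.7 ± 10.4 against 8.13 ± 2.21 CPM (log2 3.11, SE 0.24, adjusted p 4.22e-09) and the chemokine receptor Ccr6 at 107 ± 11.4 against 16.8 ± 1.18 (2.67, SE 0.19). Ramp1 (90.1 against 13.3 CPM, 2.73), Tnfsf8 (200 against 31.8, 2.58), the transcriptional regulator Tox2 (152 against 23.5, 2.65), Bmp2 (92.0 against 15.1, 2.61) and the adhesion molecule Alcam (179 against 31.0, 2.57) were higher. Palld (2.99), Galnt17 (2.80), Cacnb2 (2.72) and Unc5c (2.53) were higher too. Among the falls were Tbx21 at 24.5 ± 13.8 against 107 ± 13.4 CPM (−2.10), Ncr1 at 36.9 ± 34.6 against 140 ± 7.98 (−1.88), Klrb1c (20.7 against 96.0, −2.20), Ccr9 (49.9 against 205, −2.03) and Klrc1 (−1.61). The interferon gamma gene Ifng was at 21.01 ± 26.5 against 64.9 ± 1.62 CPM (−1.55, adjusted p 0.00491), but at −0.67 in one sample and −4.36 in the other. Slc6a20a (−3.14), Cdk14 (−1.97), Gda (−1.75), Ust (−1.68), Abi3bp (−1.60) and Irak3 (−1.54) were lower as well. Cd4 and Ccr6 were naming markers of the LTi-like subset, and Tbx21, Ncr1 and Ifng of the NCR+ subset. Tnfsf8, Galnt17, Cacnb2 and Unc5c were among the leading genes of cluster 8, and Slc6a20a, Cdk14, Gda and Abi3bp of cluster 0. These genes therefore restate the cluster mix in part. Pairing within cluster by nearest depth left 93 genes, of which 70 were among the 1054, and turned Cacnb2 (−0.11) and Klrc1 (0.51). There, of 60 named genes other than Il22, list examples included, 36 no longer passed and 9 turned. Pairs within 10% in depth left 82 genes, of which 65 were among the 1054, and turned Klrc1 (0.41), Ifng (0.73) and Galnt17 (−0.03). With these pairs 36 of the 60 no longer passed and 10 turned. Without the sample block 426 genes passed and under DESeq2 320, and the count ran from 82 to 1187 over all alternatives.

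Among the lists by Pdcd1 status, 15 checkpoint and costimulatory receptors other than Pdcd1 had 1 higher and 6 lower (2 and 8 adjusted over the list alone). The inhibitory receptor Btla was higher (34.3 against 4.42 CPM, log2 2.93), while Cd226 (143 against 323, −1.18), Nt5e (−0.92) and the costimulator Icos (352 against 619, −0.82) were lower. Effector cytokines had 6 of 17 higher and 5 lower (7 and 7 adjusted over the list alone), with Il17f (73.8 against 16.8 CPM, 1.97), Tnfsf11 (1655 against 793, 1.04), Ltb (0.92) and Ifng. The IL-23, IL-1 and STAT3 axis had 5 of 21 higher and 1 lower (5 and 5 adjusted over the list alone), with Socs3 (1.46), Socs1 (0.94), Il1r1 (0.82) and Il18r1 (−0.50). NF-kB targets had 6 of 15 higher and 2 lower (8 and 2 adjusted over the list alone), as in Cd83 (853 against 387 CPM, 1.15), Tnip1 (0.53), Nfkb1 (0.27) and Bcl2a1d (−1.21). Of 24 immediate early genes 5 were higher and 4 lower (6 and 4 adjusted over the list alone), with Egr1 (0.73), Atf3 (0.45), Fosb (0.30) and Dusp1 (−0.42). Tissue residency and migration had 5 of 15 higher and 5 lower (6 and 7 adjusted over the list alone), with Cxcr4 (1.24), Itga4 (0.79) and Rgs1 (−0.80). MHC class II had 3 of 8 higher (3 and 0 adjusted over the list alone), with Cd74 at 374 ± 161 against 204 ± 10.5 CPM (0.85), H2-Eb1 (0.97) and H2-Aa (0.84). These 3 turned in cells paired within cluster by nearest depth, to −0.61, −0.42 and −0.76, as did Egr1 (−0.21) and Fosb (−0.12). With pairs within 10% all 5 turned again, Cd74 (−0.69, adjusted p 9.53e-04) and H2-Aa (−0.88, 0.00176) past the threshold, and Cd83 (−0.02) turned too.

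Among metabolic lists by Pdcd1 status, glycolysis had 2 of 19 higher and 1 lower (3 and 1 adjusted over the list alone), with Hk3 (26.4 against 4.66 CPM, log2 2.42), Pfkfb3 (0.81) and Pfkp (−0.39). All 3 polyamine genes past the threshold, of 13, were higher (3 and 1 adjusted over the list alone), Odc1 (3183 against 1998 CPM, 0.67), Arg1 (0.59) and Azin1 (0.43). Antioxidant enzymes had 2 of 21 higher and 1 lower (2 and 1 adjusted over the list alone), Gpx1 (0.73), Gpx4 (0.46) and Gclc (−0.75), and lipid and sterol synthesis 1 of 21 higher (0 and 0 adjusted over the list alone), Elovl6 (0.70). In cells paired within cluster by nearest depth Pfkp (0.08) and Gclc (0.03) turned, and with pairs within 10% Pfkp (0.02). Of 12 cell cycle genes 2 were higher (4 and 0 adjusted over the list alone), Top2a (1.22) and Stmn1 (34.1 ± 43.1 against 7.13 ± 3.12 CPM, 1.88), the last at −0.36 and 2.67 in the samples. Of 6 aryl hydrocarbon receptor targets 0 were higher and 1 lower (0 and 4 adjusted over the list alone), Ahrr (5.54 against 14.8 CPM, −1.42), with Ahr at −0.39 (adjusted p 0.0735). In the Notch pathway 0 of 10 passed (0 and 3 adjusted over the list alone), with Hey1 at −0.75 (0.0533), and in oxidative phosphorylation 0 of 35 (0 and 0). In camera 2 of 15 lists passed, checkpoint receptors lower (adjusted p = 0.0235, or 0.938 with an estimated correlation) and aryl hydrocarbon receptor targets lower (0.0334, or 0.938), so 0 passed with an estimated correlation. The adjusted p of the other lists ran from 0.281 (cell cycle, up) to 0.969 (antioxidant enzymes, down). In fry 0 lists passed on balance and 1 with genes in either direction. The signs of median and mean differed in the IL-23 axis (−0.12 and 0.12, tested up) and glycolysis (−0.07 and 0.11, tested down), while lipid synthesis (0.03 and 0.00) and antioxidant enzymes (0.09 and 0.02) tested down with a median above 0.

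**Figure D2:**
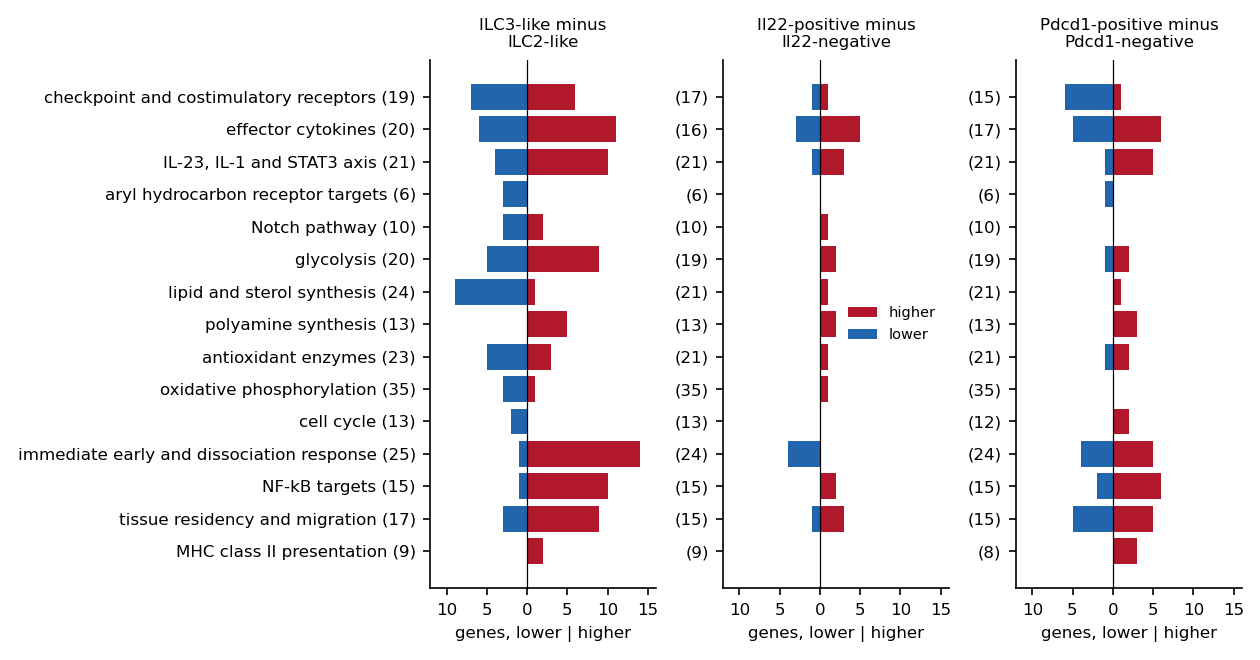
Number of genes past the threshold (x axis, lower in blue to the left, higher in red to the right) in each of 15 lists (y axis, measured genes in brackets), for ILC3-like minus ILC2-like, Il22-positive minus Il22-negative and Pdcd1-positive minus Pdcd1-negative cells; bars are counts and carry no interval. Immediate early genes had 14 higher and 1 lower in the first comparison, 0 and 4 in the second and 5 and 4 in the third.

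Counted cell by cell, Il22 was seen more often in Pdcd1-positive ILC3-like cells. In WT sample 1, 96 of 136 Pdcd1-positive cells had an Il22 UMI (70.6%, 62.2 to 78.1) against 349 of 779 Pdcd1-negative cells (44.8%, 41.3 to 48.4), a difference of 25.8 points. In WT sample 2 the counts were 105 of 141 (74.5%, 66.4 to 81.4) against 300 of 561 (53.5%, 49.3 to 57.7), or 20.99 points. Thinned to 3000 UMIs, with Pdcd1 status called again, the Il22-positive shares were 64.9 against 41.9% (13 and 106 cells left out) and 75.5 against 49.0% (22 and 80 left out). Within the clusters of WT sample 1 the Il22 gaps were smaller, at 42.3 against 39.3% in cluster 0 (thinned 38.9 against 35.1), 70.5 against 65.0% in cluster 1 (69.2 against 66.97) and 81.8 against 68.3% in cluster 8 (36 of 50 cells against 63.04%). In WT sample 2 they were 78.3 against 64.3% in cluster 1 (thinned 44 of 55 cells against 59.5%) and 76.0 against 53.3% in cluster 8 (78.4 against 56.8). Cluster 0 ran the other way there, at 2 of 8 cells against 48.9% (thinned 1 of 6 cells against 43.2%).

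**Figure D3:**
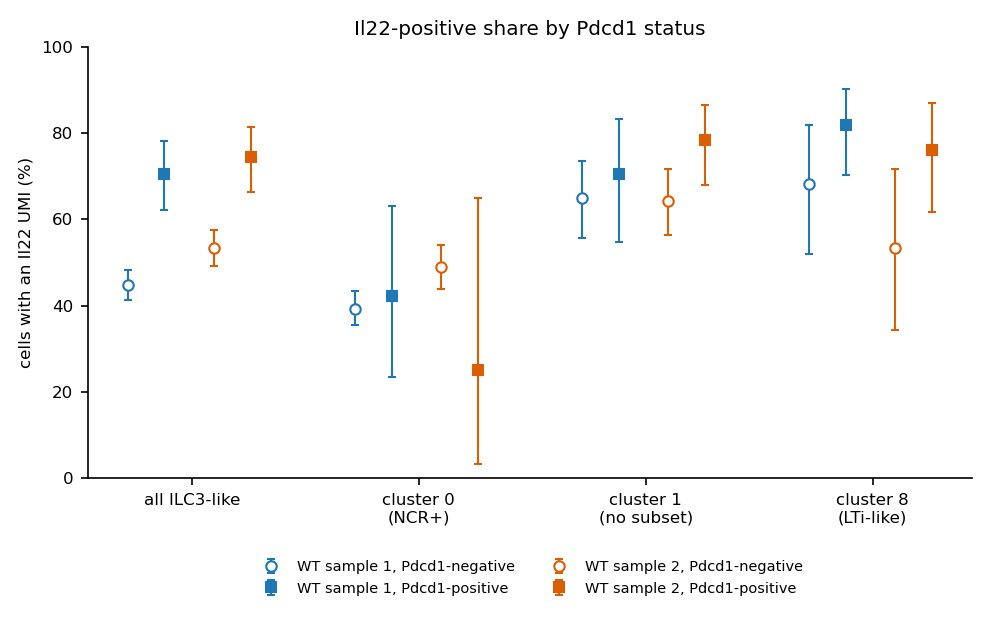
Share of cells with an Il22 UMI in percent (y axis) for all ILC3-like cells and for clusters 0, 1 and 8 (x axis); filled squares are Pdcd1-positive and open circles Pdcd1-negative cells, blue WT sample 1 and orange WT sample 2, with exact 95% intervals. Over all ILC3-like cells the shares were 70.6 against 44.8% and 74.5 against 53.5%.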

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

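The tests on the cluster mix, on depth and on free Pdcd1 RNA by thinned shares were chosen only after the results were seen. So were those on T cell markers in the LTi-like cluster and on Il22 in the B cell cluster. The ILC2 marker test was written before. No biological explanation was tested, because the design has 1 group of mice.

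Pdcd1 was higher in Il22-positive than in Il22-negative ILC3-like cells (0.94). If the mix of clusters caused this, cells of the same cluster and depth should show a value near 0. Paired within cluster by nearest depth, Pdcd1 was at 0.16 (SE 0.19, limit 0.47), but positive cells stayed deeper (median 5576.5 and 5186 against 5411.5 and 4564 UMIs). With pairs within 10% in depth Pdcd1 was at 0.0822 (SE 0.16). If deeper cells caused it, matching for depth alone should remove it, but Pdcd1 stayed at 0.89 (SE 0.13), which argues against depth. The rise is therefore consistent with Il22-positive cells lying more often in clusters 1 and 8. With 317 and 247 cells per arm in the pairs within 10%, a smaller rise within clusters may remain.

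Pdcd1 was far lower in the NCR+ cluster than in the LTi-like cluster. Free RNA spread evenly over droplets should give close shares at equal depth, yet the 95% intervals of the thinned shares lay at least 34.1 points apart, which argues against it as the source of the difference. T cells caught with LTi-like cells should bring T cell receptor complex genes along with Pdcd1. The median level of T cell markers in the LTi-like cluster was 4.16% of that in the Foxp3 cluster (highest 8.93% for Cd3e, limit 45.8%), while Pdcd1 was at 91.5%, which argues against T cell doublets.

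A cluster of B cell genes (cluster 6, with Ebf1, Cd79a and Ms4a1) came through a sort that gated out CD19 and B220, and it also held Il22 (317 CPM pooled) and Il23r (813 CPM). Free RNA should give Il22 at a like level in ILC2-like cells, but the smaller ratio of the samples was 37.0, which argues against it. Doublets with ILCs may fit its UMI ratio of 1.81 and its 24.4% of cells with high Scrublet scores. The ILC2 marker test asked for a median of at least 5% of the ILC2-like level if doublets were the cause and under 2% if not, both written before. The median of 5 genes was 5.38%, which met the first. The genes ran from −4.10 (Rnf128) through 3.81 (Il5), 5.38 (Il17rb) and 5.63 (Calca) to 13.1% (Il1rl1). After this was seen the rule was changed, to a lower quartile of at least 5% for doublets and an upper quartile under 2% against them. Under the changed rule the cause stays open.

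Other surprises were clusters with T or B cell genes, after a sort that gated out CD3, TCRb, CD19 and B220. A cluster with Trdc held 10.2 and 6.54% of cells, a Foxp3 cluster 3.12 and 2.66% and the B cell gene cluster 5.43 and 5.03%. A further cluster, of high UMI counts, held 4.10 and 2.59%. It had a UMI ratio of 2.27 and 63.1% of cells with high Scrublet scores, and it was kept out of every class.

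Whether the difference by Il22 status itself differed between clusters was tested by interaction. For clusters 0 and 8 there were 5 such genes (Cdk14, St7, Ikzf2, Tnfrsf9 and Bcl2l11), for clusters 1 and 8 there were 9 (Csmd1, Cdk14, Prickle1, Cxcr4, Tmcc1, Ikzf2, Kcnq5, Dnajc6 and Man1a), and for clusters 0 and 1 edgeR called 0 (430 of 8531 at an unadjusted p under 0.05). Csmd1 was at −3.83 in cluster 1 and 5.17 in cluster 8 (adjusted p 4.06e-06), and Cdk14 at −0.33 in cluster 0 and 2.87 in cluster 8 (0.00722). Pdcd1 showed no such difference (adjusted p 0.988, 0.975 and 0.906). By Pdcd1 status edgeR called 0 genes for clusters 1 and 8 (333 of 6505 at an unadjusted p under 0.05), with Il22 at an adjusted p of 0.998.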

How the results depend on the processing

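Besides the Pdcd1 and Il22 results that answer a comparison, 269 pairs of a named gene and a comparison had 3284 values under tested alternatives. Of these 2732 stayed the same, 529 no longer passed, 0 newly passed and 23 reversed. Of 538 values from 1 sample alone, 96 moved and 1 reversed. A value counted as unmoved within 1 SD of the values of the 2 samples, a limit that 2 samples nearly always meet. Named rises and falls had also been chosen for the same direction in both samples. These counts are therefore no test of stability. With 1 group of 2 samples no other split of the samples was possible, and leaving 1 sample out gave a value with no test. The largest cluster alone was not run for Pdcd1 status, because cluster 0 held 26 and 8 Pdcd1-positive cells and the minimum was 20 per sample. Protein tags were not run. Single lanes, the Trdc cluster, matching for depth alone, pairs within 10% in depth and lists without naming markers were alternatives chosen after seeing the data. The cause of each change was not tested.

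Without the sample block, which pairs the cell groups, Pdcd1 was at −0.75 between ILC3-like and ILC2-like cells, 1.33 in cluster 1 and 0.99 by Il22 status. The count by Il22 status went to 0 genes and that by Pdcd1 status to 426. Under DESeq2 Pdcd1 was at −0.79 between the classes and 1.35 in cluster 1, with 35 genes by Il22 status and 320 by Pdcd1 status. With no expression filter 471 genes passed by Il22 status.

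In lane 1 Pdcd1 was at −0.89 between the classes and 0.80 by Il22 status, Kcnq5 turned to 0.0178 by Il22 status, and 17 and 532 genes passed by Il22 and Pdcd1 status. In lane 2 Pdcd1 was at −0.61 between the classes and 1.06 in cluster 1, with 518 genes by Pdcd1 status. With finer clusters Pdcd1 was at −0.46 between the classes and 0.55 by Il22 status, Xcl1 turned to 0.0111 by Il22 status, and 114 and 685 genes passed. The ILC3-like share became 27.4 and 41.7% and the T cell-like share 12.3 and 8.98%, with finer clusters 6 and 10, of best class ILC3, left unnamed. With the Trdc cluster added, Blk (−0.47) and Il17a (−0.0301) turned by Il22 status, Pdcd1 was at 0.47 and 546 genes passed.

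In cells paired within cluster by nearest depth Pdcd1 was at 0.16 by Il22 status, with 54 genes. By Pdcd1 status 93 genes passed and Il22 was at 0.32, while Cacnb2 (−0.11), Klrc1 (0.51), Pfkp (0.0780), Gclc (0.0325), Egr1 (−0.21), Fosb (−0.12), Cd74 (−0.61), H2-Eb1 (−0.42) and H2-Aa (−0.76) turned. With pairs within 10% Pdcd1 was at 0.0822 by Il22 status, with 13 genes. By Pdcd1 status 82 genes passed and Il22 stayed past the threshold at 0.40, while Galnt17 (−0.0337), Klrc1 (0.41), Ifng (0.73), Pfkp (0.0249), Egr1 (−0.17), Fosb (−0.13), Cd83 (−0.0236), Cd74 (−0.69), H2-Eb1 (−0.65) and H2-Aa (−0.88) turned. In the largest cluster alone Pdcd1 reversed to −0.28 by Il22 status, with 48 genes. Calling a cell positive at 2 or more UMIs gave 425 genes by Il22 status. Leaving out cycling cells gave 459 genes by Il22 status and 692 by Pdcd1 status.

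Without naming markers 5 lists still passed camera between the classes, effector cytokines in place of the IL-23, IL-1 and STAT3 axis. With an estimated correlation camera passed 0 lists between the classes, in place of 5, and 0 by Pdcd1 status, in place of 2. By Pdcd1 status that version rests on 1 residual degree of freedom, so the loss says little about correlation. Thinned to 3000 UMIs the Il22-positive share of Pdcd1-negative cells in WT sample 2 was 49.0%. Leaving out high Scrublet scores put the ILC3-like share of WT sample 1 at 37.9%, and leaving out low-quality cells its epithelial-like share at 0.436%. From 1 sample alone, Stmn1 by Pdcd1 status ran from −0.36 to 2.67. Pdcd1 ran from −1.30 to −0.36 between the classes, −5.76 to −3.40 in cluster 0, 0.87 to 1.94 in cluster 1, 2.53 to 3.81 in cluster 8 and 0.89 to 0.97 by Il22 status, and Il22 from 1.03 to 1.08 by Pdcd1 status.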

Other observations

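The MHC class II and cluster tests reported here were picked only after the results of 45 tests (15 lists in 3 clusters) had been seen.

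Antigen presentation genes were higher in the LTi-like cluster 8. Of 7 measured MHC class II genes 6 were higher there (6 and 0 adjusted over the list alone), with Cd74 at 2.45, H2-Aa at 2.53, H2-Eb1 at 2.46, H2-Ab1 at 1.70, H2-DMb1 at 1.82 and H2-DMa at 1.37. In the NCR+ cluster 0 and in cluster 1, 4 were lower each and 0 higher, Cd74 among them at −1.27 and −1.18. The 3 contrasts sum to 0, so these falls are the other side of the rise in cluster 8 and add no finding of their own. In camera the list was higher in cluster 8 (adjusted p 0.000118) and, for the same reason, lower in cluster 0 (0.0203) and cluster 1 (5.81e-06). With an estimated correlation, 0.845 for this list, 0 of the 45 tests passed, in place of 7. That version rests on 2 residual degrees of freedom, so a list could hardly pass it and the loss decides little. In fry 0 of the 45 passed on balance in one direction, with this list at 0.135 in cluster 8, 0.190 in cluster 0 and 0.417 in cluster 1, and 28 passed with genes in either direction. The other 4 of the 7 in camera were checkpoint receptors (0.0437) and aryl hydrocarbon receptor targets (0.0437) higher in cluster 0, the latter lower in cluster 8 (0.0456), and immediate early genes higher in cluster 1 (0.0173).

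Pdcd1 was not limited to ILC3-like cells. In WT samples 1 and 2 it was at 514 and 328 CPM in the Foxp3 cluster 12, 302 and 573 CPM in the LTi-like cluster 8, 329.9 and 308 CPM in the unnamed cluster 10 with Lef1, and 304 and 334 CPM in the ILC2-like cluster 4, so the order turned between the samples. Among ILC2-like clusters a Pdcd1 UMI was seen in 48.7 and 53.4% of cluster 4 cells (Calca, Hs3st1), 33.0 and 38.1% of cluster 9 cells (Il1rl1, Il5) and 24.3 and 17.4% of cluster 3 cells (Kcnd2, Angpt1). The Trdc cluster 2 had Pdcd1 at 215 CPM beside Il23r at 2120 CPM, Cd163l1 at 735 CPM, Trdc at 682 CPM and Il17a at 221 CPM.

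Haemoglobin genes headed the NCR+ cluster 0 through few cells. Hbb-bs had 1757 UMIs in 6 of 1026 cells, Hba-a1 724 UMIs in 4 cells, Hba-a2 571 UMIs in 4 cells and Hbb-bt 351 UMIs in 2 cells, although TER119 was gated out. Igkc, a plasma cell gene, had a UMI in 99.6% of all cells, with 99.4% in ILC3-like and 99.5% in ILC2-like cells, and Jchain in 87.6%.

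In the deposited cell tables the score on PC_13 split the samples. It ran from −3.93 to 0.31 in WT sample 1 (median −2.25) and from 0.60 to 5.03 in WT sample 2 (median 3.24). The cause of this split was not tested.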
